A study of Mus musculus with 12 samples.

How the data were processed

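The series measured gene expression in macrophages grown from the bone marrow of C57Bl/6 mice in macrophage colony-stimulating factor. Each of 4 groups held 3 biological replicates, lettered A, B and C in the labels, for 12 arrays in all. Cells received 100 ng/ml lipopolysaccharide (LPS) or none for 18 h, were given new medium, rested for 2 h, and then received 100 ng/ml LPS or none. The length of the last stimulation is not given in the sources used here. Per the labels' protocols, total RNA was isolated with TriFast and labelled with biotin and PE by the standard procedure of Affymetrix.

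The deposited values were intensities on a linear scale, 1 per probe set and array. The program, the background correction and the scaling that made these intensities are not given in the sources used here, and the scale was read from the values. The table held 45101 probe sets, 64 of them controls. Gene symbols came from the platform annotation, 34945 probe sets with 1 symbol, 932 with several and 9160 unnamed here. Symbols were updated by Entrez identifier through the RefSeq gene table of assembly GRCm38.p6, which matched 34741 probe sets, and 204 kept the platform's symbol. That table served for names only, and no coordinates were used.

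Intensities were transformed as log2(value + 16), and no further normalization was applied. Fold changes are on this scale, which understates the change of dim genes. Each gene was represented by the probe set with the highest mean over the 12 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. Probe sets of the same gene had opposite calls for 1 gene, Pnkd, in the first response and in the comparison of levels after LPS. Probe sets with several symbols or none entered no comparison of the report.

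Differential expression was tested with limma 3.58.1 in R 4.3.3. A single fit of the 4 group means used all 12 arrays, with 8 residual degrees of freedom and 1.71 prior degrees of freedom. The 5 contrasts were the first LPS response (LPS once minus untreated), the pretreatment effect (pretreated minus untreated), the second LPS response (restimulated minus pretreated), the interaction (second minus first response) and the level after LPS (restimulated minus LPS once). A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast and at least 2-fold, and the interaction needed a 2-fold difference between the 2 responses. All adjusted p-values of single genes are from limma, and errors beside log2 fold changes are its standard errors (SE). The first response and the pretreatment effect share the 3 untreated arrays. Their overlap of calls was set beside the value of 20 simulations without effects and beside that of independent lists, and 3 arrays could not be split into sets of 2 or more.

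Genes higher in the first response are called induced, and genes lower in it repressed. They were classed by the interaction and, separately, by the level after LPS. Because a gene chosen for a large first response enters the interaction with that response, the same classes were counted in 20 simulations with equal first and second responses.

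Before the data were examined, 31 gene lists were fixed, covering inflammatory, metabolic and housekeeping genes, macrophage identity and markers of other cell types. They named 615 genes, of which 555 were measured. Each list was tested in each contrast with limma's camera at a preset correlation of 0.01 between genes, and p-values were adjusted over the 155 tests. With the correlation estimated from the data, 0 of the 61 tests called in this way passed. The fry test, which asks whether a list's genes moved on balance in 1 direction and does not compare them with other genes, called 52 of the 155, and 42 of the 61 were among them. Members were counted over all genes tested and adjusted over the list alone.

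The genes named in the text were set by a rule fixed before the data were examined. For each contrast it took the 10 largest increases and the 10 largest decreases among called genes whose groups of arrays did not overlap, with no condition on overlap for the interaction. For each list it took up to 4 called members with the largest changes or, where fewer than 2 were called, the 2 members with the largest changes. Among induced genes it took the 10 highest second responses not called reduced and the 10 most negative interactions. Tnf, Il6, Il1b, Il10, Il12b, Ptgs2, Nos2, Cxcl10, Ccl5, Lcn2, Fpr1, Fpr2, Marco, Irak3, Tnfaip3, Tlr4 and Cd14 were named in any case, of which Fpr1 was not analysed here because no probe set carried it as its symbol. Not every gene that the rule takes is reported here.

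The replicate letters were checked for pairing through the correlation of the arrays' deviations from their group means. The 18 pairs of arrays with the same letter had r from 0.25 to 0.656, with a median of 0.361. The 36 pairs with different letters had r from -0.482 to 0.0134, with a median of -0.198. In 36 of 36 cases an array's best match in another group carried its own letter. The pairing therefore comes from the data and from the letters of the labels, which do not say what the letters share, and values from a fit with the letter as a block stand beside some of the results it moved.

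The computation was tested on simulated arrays of 18193 genes, in which 50 genes each were changed 2-fold, 3-fold, 4-fold and 8-fold. For the first response it recovered 44%, 90%, 98% and 96% of these, and for the pretreatment effect 46%, 96%, 96% and 100%. For the second response the shares were 48%, 90%, 92% and 98%, for the interaction 46%, 80%, 92% and 98%, and for the level after LPS 32%, 94%, 98% and 98%. Calls among unchanged genes numbered 0 for the first response, 2 for the pretreatment effect, 0 for the second response, 7 for the interaction and 1 for the level, and 0 changed genes were called in the wrong direction. The simulated arrays had independent normal noise, without paired letters and without a deviating array. Changes were added in full on the log2 scale, also to dim genes, whose changes the real scale shrinks. The shares may therefore overstate the recovery in the data.

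Alternatives changed 1 choice at a time, except for the block without the restimulated replicate C array, and their effect is given in the closing section. They covered the pseudocount (1 or 64), quantile normalization, centring each array on its median, leaving out dim genes, the mean of all probe sets of a gene, and leaving out probe sets with shared targets. They also covered a prior that follows the mean level, fits of only the groups compared, the replicate block, the threshold, and leaving out each array in turn. Array weights and that exception were added after seeing the data. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.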

Results

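The series asked how macrophages that have already met lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria, respond when they meet it again, a setting known as LPS tolerance. Macrophages grown from mouse bone marrow were pretreated for 18 h with 100 ng/ml LPS or left without, rested for 2 h in new medium, and then given 100 ng/ml LPS or none. The 4 groups of 3 biological replicates are called untreated, LPS once, pretreated and restimulated. RNA of the 12 cultures was measured on 12 arrays, and 18193 genes were tested.

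The arrays had similar medians, from 29.72 to 31.65 intensity units on 11 of them and 31.41 on the restimulated replicate C array. That array stood apart above the median. Its mean intensity was 246.7, against 310 to 317 on the other 11 arrays, and its 75th percentile was 119.9, against 156.1 to 207. Over the 6204 genes of mid-range intensity, between 100 and 1000, its log2 values lay at a median of -0.52 from the other restimulated arrays, and 92% of these genes were lower. On the other 11 arrays the median lay between -0.06 and 0.09, where restimulated A and B were compared with each other only. With replicate C in their reference the medians of A and B were 0.2 and 0.29. Control transcripts added from outside the cells were lower as well, with a median of -0.33 over 24 probe sets. Without this array the numbers of called members changed in 44 of the 155 pairs of a gene list and a contrast, by 6 genes at most, and values without it stand beside some of the results that it moved.

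**Figure D1:**
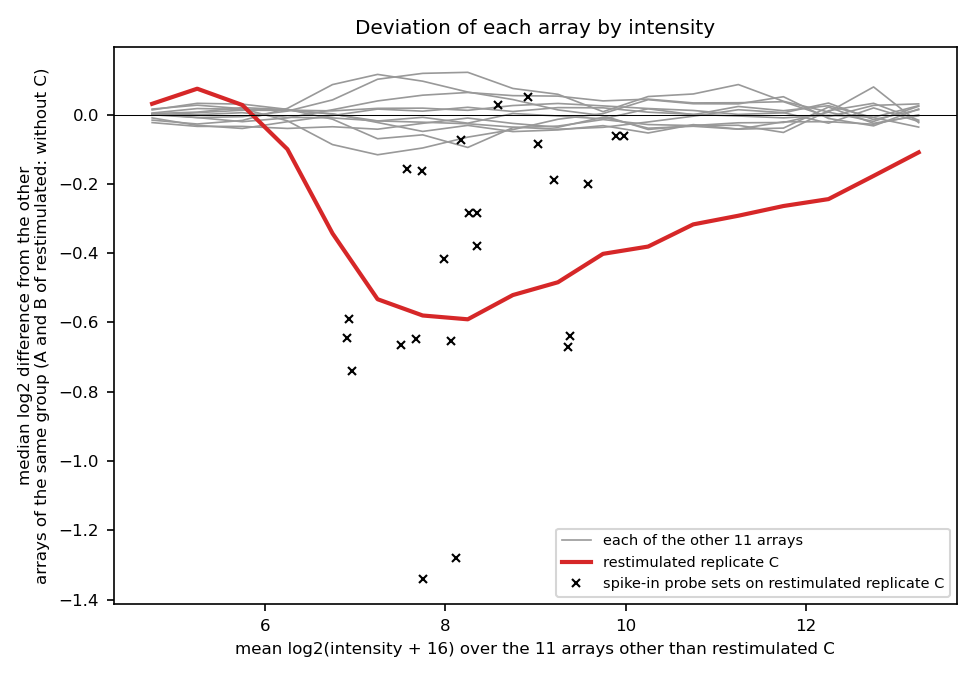
Median log2 difference of each array from the other arrays of its group, against the mean log2 intensity over the 11 arrays other than restimulated replicate C, as 1 line per array, with crosses for the control transcripts of the restimulated replicate C array. That array (thick line) lay at a median of -0.52 over the 6204 mid-range genes, and the other 11 arrays (thin lines) between -0.06 and 0.09, with restimulated A and B compared with each other only.

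The first comparison, LPS once against untreated, asked what LPS did to cells that had not met it before. Il6, a cytokine of acute inflammation, rose 199-fold, a log2 change of 7.64 ± 0.61 (SE, n = 3 per group, limma adjusted p = 2.62e-05). Its log2 intensity was 4.82 ± 0.0806 in untreated cells and 12.46 ± 0.331 after LPS (SD, n = 3). The neutrophil-attracting chemokines Cxcl1 and Cxcl3 rose by 7.22 ± 0.86 and 6.87 ± 1.24, and Acod1, the enzyme that makes itaconate, by 6.43 ± 0.82. Tnf rose by 4.32 ± 0.29, Il1b by 5.19 ± 0.73, Il10, an anti-inflammatory cytokine, by 5.27 ± 0.21, and Il12b, a subunit shared by interleukin 12 and interleukin 23, by 5.49 ± 0.37. Cxcr4, the receptor of the chemokine Cxcl12, changed by -5.76 ± 0.45, Rgs2, a regulator of G protein signalling, by -5.57 ± 0.34, and Sesn1, a stress-response gene, by -5.33 ± 0.44. Nos2, the inducible nitric oxide synthase, had a log2 change of 0.84 ± 0.18, Tlr4, the LPS receptor, of -0.95 ± 0.28 and its co-receptor Cd14 of 0.92 ± 0.20, all under the 2-fold minimum. Cd14 had log2 intensities of 13.55 to 13.7 after LPS once, near the top of the array scale, so its rise may be understated.

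Among 35 measured interferon-induced genes, 29 rose and 0 fell, and 31 rose adjusted over the list alone. Limma called 0 of them lower, and 0 were lower at an unadjusted p under 0.05. Oasl1 rose by 5.18, the antiviral genes Gbp2 by 4.81 and Ifit1 by 4.77, and the list stood above other genes (camera adjusted p = 1.49e-11, adjusted p = 0.547 with an estimated correlation). Of 28 cytokines and growth factors 17 rose and 1 fell, with 18 and 1 adjusted over the list alone (camera adjusted p = 3.23e-08, adjusted p = 0.203 with an estimated correlation). Of 26 chemokines 16 rose, also adjusted over the list alone, among them Ccl5 by 5.17 (camera adjusted p = 2.24e-08, adjusted p = 0.203 with an estimated correlation). The antimicrobial and acute phase list had 12 of 21 members higher, also adjusted over the list alone, led by Saa3 at 5.79 and Lcn2, which binds bacterial siderophores, at 5.15 (camera adjusted p = 7.66e-07, adjusted p = 0.239 with an estimated correlation). Costimulatory and coinhibitory ligands had 10 of 15 higher, also adjusted over the list alone, with Cd40 at 5.86 and Cd274 at 3.72 (camera adjusted p = 6.07e-07, adjusted p = 0.211 with an estimated correlation).

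Of 30 negative regulators of Toll-like receptor signalling, 18 rose and 2 fell, and 18 and 3 did adjusted over the list alone (camera adjusted p = 4.96e-07, adjusted p = 0.239 with an estimated correlation). Socs3, which restrains cytokine receptors, rose by 5.66, the phosphatase gene Dusp2 by 5.13, Tnfaip3, which encodes the A20 protein, by 3.91 and Irak3, an inhibitor of interleukin 1 receptor-associated kinases, by 2.25. Toll-like receptor 4 signalling had 8 of 26 members higher, also adjusted over the list alone, with Rel at 3.22 and Nfkb2 at 2.32 (camera adjusted p = 0.00321, adjusted p = 0.556 with an estimated correlation). Immediate-early and stimulus-induced factors went both ways, 9 of 30 higher and 3 lower, also adjusted over the list alone, with Maff at 3.86 and Fos at -2.59 (camera adjusted p = 0.0303, adjusted p = 0.481 with an estimated correlation). In the survival, apoptosis and inflammasome list 10 of 21 rose and 1 fell, also adjusted over the list alone, with Gadd45b at 3.73 and the inflammasome sensor Nlrp3 at 3.05 (camera adjusted p = 0.00118, adjusted p = 0.239 with an estimated correlation).

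Glycolysis and hypoxia-induced genes had 8 of 22 members higher, also adjusted over the list alone, with Pfkfb3, a regulator of glycolytic flux, at 4.14, Adm at 3.69 and the glucose transporter Slc2a1 at 2.22 (camera adjusted p = 0.0056, adjusted p = 0.641 with an estimated correlation). Limma called 0 of 29 genes of the citric acid cycle and respiratory chain, 17 of which were lower at an unadjusted p under 0.05, and the list stood below other genes (camera adjusted p = 0.000131, adjusted p = 0.589 with an estimated correlation). Idh1 and Mdh1, cytosolic relatives of that cycle's enzymes, had log2 changes of -0.99 and -0.95, and both were called lower after quantile normalization. In the cell cycle list 8 of 35 fell and 1 rose, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.622 with an estimated correlation). The replication licensing genes Cdt1 and Mcm7 changed by -2.61 and -1.77, and the proliferation marker Mki67 by 2.51. After quantile normalization 4 of the 35 were lower. Liver X receptor targets and lipid synthesis genes had 4 of 17 lower, also adjusted over the list alone, among them the desaturase gene Fads1 at -2.86 and Abcg1, a cholesterol exporter, at -1.75 (camera adjusted p = 0.00582, adjusted p = 0.428 with an estimated correlation).

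Over all genes, limma called 709 higher and 1655 lower after LPS once. These counts stayed within 1.5 times when any array was left out. Of the 96 called genes that the naming rule takes from this comparison, 88 kept their call without any of the 12 arrays.

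**Figure D2:**
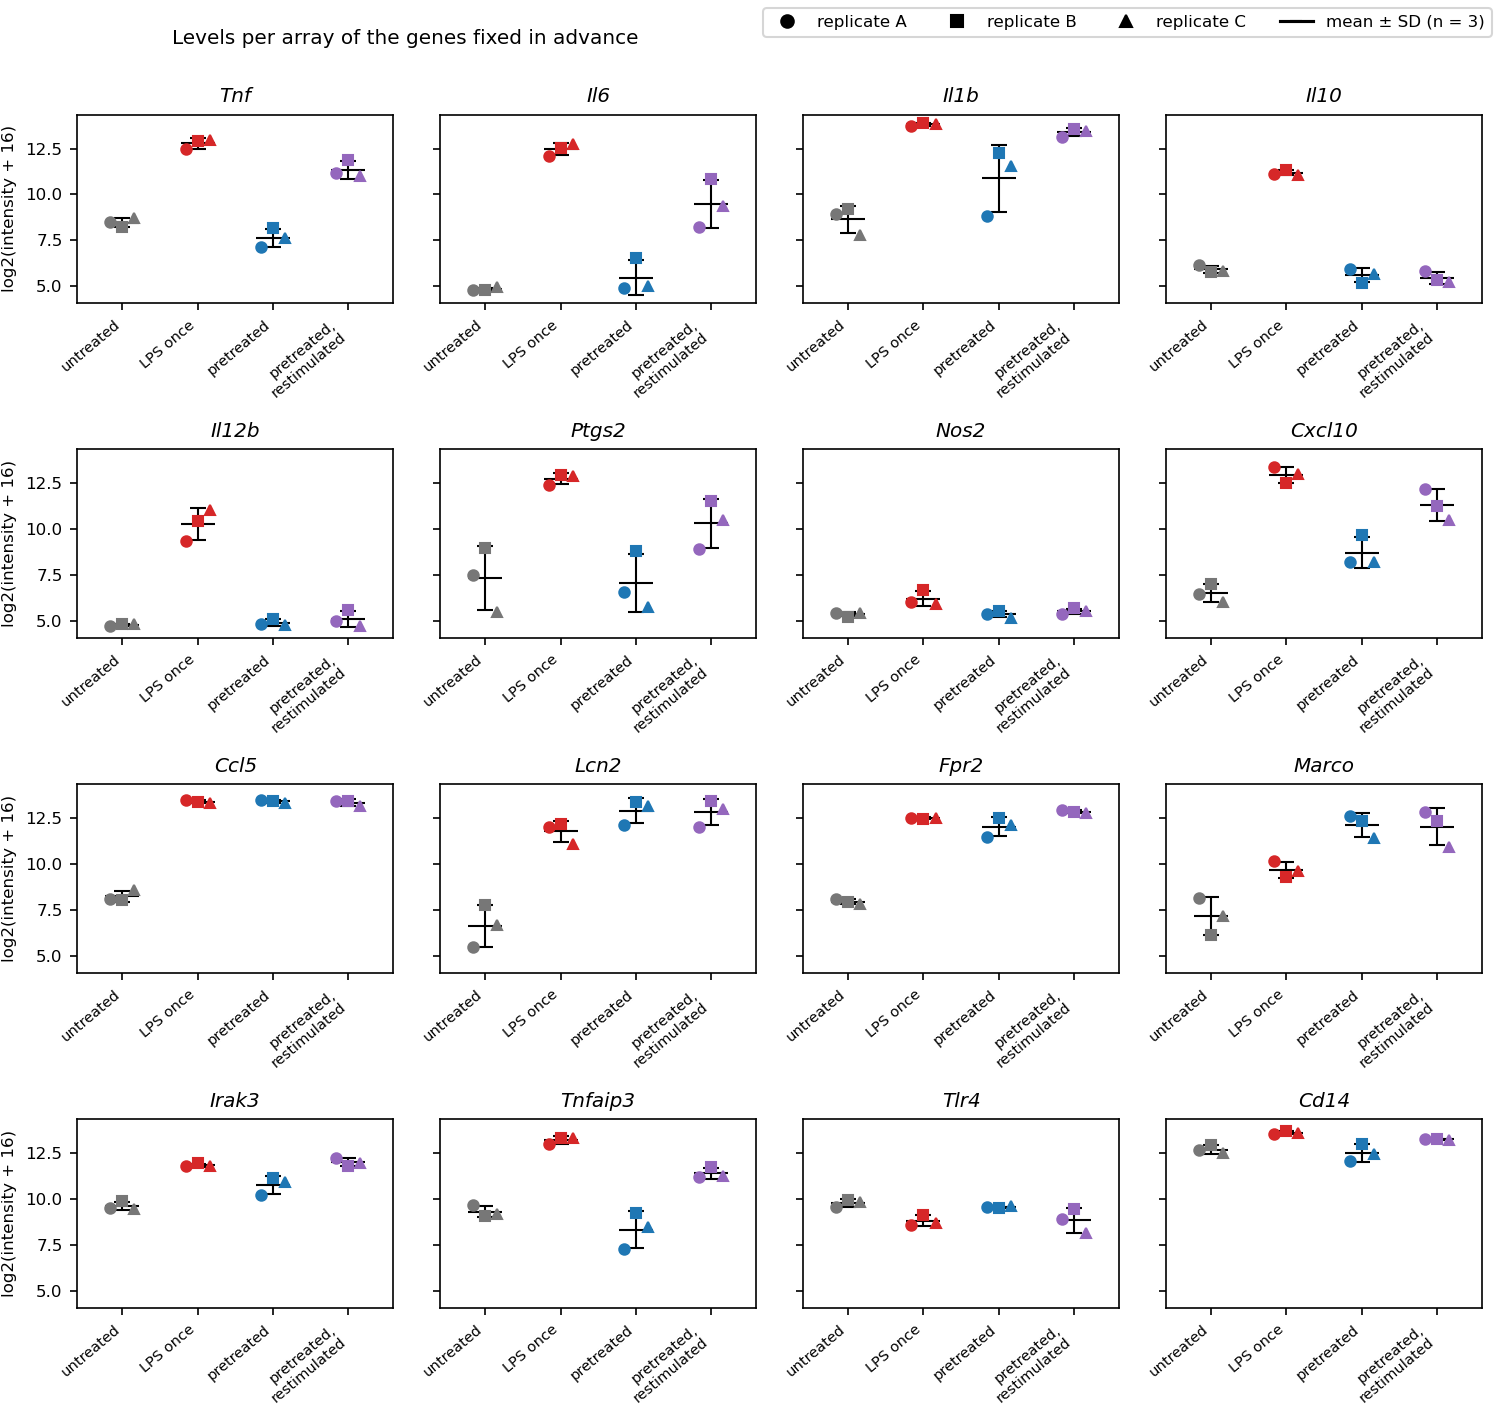
Log2 intensity of selected genes on each of the 12 arrays, by group, with the mean and SD of 3 replicates. Tnf rose in both responses, by 4.32 and 3.71, while Il10 rose by 5.27 after LPS once and had a second response of -0.12.

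The second comparison, pretreated against untreated, asked what the pretreatment had left behind after the rest. Cfb, complement factor B, rose by 6.67 ± 0.39 (SE, n = 3 per group, limma adjusted p = 6.59e-05), Lcn2 by 6.28 ± 0.60 and the acute phase gene Saa3 by 6.14 ± 0.12. The chemokine Ccl5 rose by 5.18 ± 0.14, the scavenger receptor Marco by 4.97 ± 0.61 and the formyl peptide receptor Fpr2 by 4.10 ± 0.21. Cd83, a surface protein of activated antigen-presenting cells, changed by -4.28 ± 0.29, the lipid-sensing nuclear receptor Pparg by -3.10 ± 0.38, and Kitl, which encodes stem cell factor, by -2.21 ± 0.18. Tnf, Il6 and Il1b were not called, with log2 changes of -0.83 ± 0.29, 0.63 ± 0.61 and 2.23 ± 0.73.

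Antimicrobial and acute phase genes had 8 of 21 members higher, and 11 adjusted over the list alone (camera adjusted p = 4.35e-18, adjusted p = 0.203 with an estimated correlation). Of 35 interferon-induced genes 6 rose, and 23 did adjusted over the list alone (camera adjusted p = 4.12e-22, adjusted p = 0.318 with an estimated correlation). The count over all genes was 14 with the replicate letter as a block and 12 without the restimulated replicate C array. Irf7, a transcription factor of the interferon system, rose by 3.74 and Zbp1, a nucleic acid sensor, by 3.12. For MHC class I presentation limma called 0 of 15 genes, 12 were higher at an unadjusted p under 0.05, 3 were higher adjusted over the list alone, and the list stood above other genes (camera adjusted p = 3.79e-12, adjusted p = 0.239 with an estimated correlation). Tap1, a peptide transporter, had a log2 change of 1.62, called with the replicate block and after quantile normalization, and the immunoproteasome gene Psmb8 of 1.17.

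Negative regulators of Toll-like receptor signalling had 3 of 30 members lower and 0 higher, and 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000112, adjusted p = 0.359 with an estimated correlation). At an unadjusted p under 0.05, 2 of them were higher. The phosphatase gene Dusp1 changed by -1.56. Trem2 was also among the lower members, and its change took the other sign without probe sets whose targets may be shared. Immediate-early factors had 1 of 30 lower and 5 lower adjusted over the list alone (camera adjusted p = 3.64e-05, adjusted p = 0.203 with an estimated correlation), and the first count was 3 with the replicate block and 2 without the restimulated replicate C array. For the cell cycle list limma called 0 of 35, 17 were lower at an unadjusted p under 0.05 and 2 lower adjusted over the list alone, and the list stood below other genes (camera adjusted p = 4.6e-11, adjusted p = 0.294 with an estimated correlation). With the replicate block 5 were called lower, among them Cenpa, a centromere protein, with a log2 change of -1.61.

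In all, 53 genes were higher and 56 lower in pretreated cells, and 100 and 97 with the replicate block. Leaving out an array lowered the higher genes to 32 (untreated A), 26 (untreated C), 30 (pretreated B) and 29 (pretreated C), and the lower genes to 28 (untreated A), 25 (untreated C), 37 (pretreated A) and 31 (pretreated C). Of the 35 called genes that the naming rule takes here, 19 kept their call without any of the 12 arrays, and the highest adjusted p among the others was 0.18. Of the 53 higher genes 36 were also higher in the first response, where independent lists would share 2.07, and of the 56 lower genes 30 were also lower, where they would share 5.09. A mean of 0 genes was shared in 20 simulations, which leave out the effects and so give no value for lists of this length. Both comparisons use the same 3 untreated arrays, and part of the excess may come from them.

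The third comparison, restimulated against pretreated, measured the response of cells that had met LPS before. The chemokine gene Ccl3 rose by 4.27 ± 0.28 (SE, n = 3 per group, limma adjusted p = 0.000457), Ccl4 by 3.47 ± 0.16 and Tnf by 3.71 ± 0.29. The inhibitors of inflammatory signalling Nfkbie and Socs3 rose by 3.59 ± 0.42 and 3.58 ± 0.36, Tnfaip3 by 3.06 ± 0.41, the transcription factor Ets2 by 3.66 ± 0.43 and the integrin gene Itgb8 by 3.63 ± 0.39. Il6 rose by 4.03 ± 0.61, a call that was lost without the pretreated replicate C array (adjusted p = 0.059, the highest with any array left out). On the 6 arrays of these groups alone Ccl4 kept its call, and all other genes named here as changed lost theirs. Rgs2 changed by -3.24 ± 0.34, Rassf3 by -2.77 ± 0.37 and the cannabinoid receptor gene Cnr2 by -2.67 ± 0.20. Il10, Il12b, Ccl5, Lcn2 and Marco were not called, with log2 changes of -0.12 ± 0.21, 0.20 ± 0.37, -0.07 ± 0.14, -0.07 ± 0.60 and -0.09 ± 0.61.

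Negative regulators of Toll-like receptor signalling had 12 of 30 members higher and 0 lower, and 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.49e-11, adjusted p = 0.203 with an estimated correlation). At an unadjusted p under 0.05, 3 were lower. Of 26 chemokines 5 rose, also adjusted over the list alone (camera adjusted p = 1.25e-05, adjusted p = 0.239 with an estimated correlation). Cytokines had 4 of 28 higher and 7 adjusted over the list alone (camera adjusted p = 0.00474, adjusted p = 0.496 with an estimated correlation). Toll-like receptor 4 signalling had 4 of 26 higher and 5 adjusted over the list alone, with Nfkb2 at 1.85 and the receptor gene Tlr2 at 1.55 (camera adjusted p = 0.00435, adjusted p = 0.556 with an estimated correlation). Costimulatory ligands had 4 of 15 higher, also adjusted over the list alone, with the adhesion molecule Icam1 at 1.78 and Icosl at 1.51 (camera adjusted p = 0.000167, adjusted p = 0.312 with an estimated correlation). Immediate-early factors had 3 of 30 higher and 1 lower, and 4 and 1 adjusted over the list alone, with Cebpd at 1.74 (camera adjusted p = 0.00135, adjusted p = 0.247 with an estimated correlation). Without the restimulated replicate C array 10 negative regulators, 3 chemokines, 3 cytokines, 3 members of Toll-like receptor 4 signalling and 2 immediate-early factors were higher, and 0 immediate-early factors lower.

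Limma called 0 of 35 interferon-induced genes in the second response, and 0 at an unadjusted p under 0.05 in either direction. Their list had a median of -0.0682, or 0.066 after quantile normalization (camera adjusted p = 0.684, adjusted p = 0.985 with an estimated correlation). Camera, which placed the list upwards against the sign of its median, called it without the restimulated replicate C array (adjusted p = 0.00981) and not with the replicate block or after quantile normalization (0.671 and 0.617). Mx2 and Oas3 had the widest log2 changes of the list, 0.89 ± 0.66 and -0.50 ± 0.54. Limma also called 0 of 21 antimicrobial and acute phase genes, of which 4 were higher at an unadjusted p under 0.05 (camera adjusted p = 0.0481, adjusted p = 0.641 with an estimated correlation). Camera did not call that list without the same array (adjusted p = 0.0643) or after quantile normalization (0.0895), and called it with the replicate block (0.0374). Acod1 had a log2 change of 2.64 ± 0.82.

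In all, 121 genes were higher and 234 lower in restimulated cells. The higher genes made up 34.1% of these, and 51.8% after quantile normalization (174 higher, 162 lower). Without the restimulated replicate C array 93 were higher and 93 lower. Fitted on the 6 arrays of these groups alone, limma called 1 gene higher, Ccl4, and 0 lower, with 518 and 2068 at an unadjusted p under 0.05. The higher count was 68 without pretreated A and 60 without pretreated C, and the lower count was 60, 381 and 35 without pretreated A, B and C and 463 without restimulated B. Of the 46 called genes that the naming rule takes here, 23 kept their call without any of the 12 arrays.

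The interaction tested whether the second response differed from the first, the question the design of 4 groups is built for. Il10 rose by 5.27 after LPS once and changed by -0.12 on restimulation, a difference of -5.40 ± 0.30 (SE, n = 3 per group, limma adjusted p = 2.77e-05). The differences for Shisa3, Saa3 and Il12b were -6.00 ± 0.19, -5.81 ± 0.16 and -5.29 ± 0.52, and those for Ccl5, Lcn2 and Fpr2 -5.24 ± 0.20, -5.22 ± 0.85 and -3.74 ± 0.30. Saa3, Ccl5 and Lcn2 had mean intensities of 14000, 11020 and 8237 after pretreatment, where the highest intensity on any array was 16570, so a second rise may have been cut off by the scale and their differences may be overstated. A second rise of Fpr2 as large as its first, from log2 intensities of 11.47 to 12.53, would also pass that highest value. Its difference may therefore be overstated as well. Among genes that LPS lowered in the first response, Sesn1 had a difference of 3.86 ± 0.62, Gpr65, a proton-sensing receptor, of 3.79 ± 0.57 and Susd3 of 2.76 ± 0.36. Tnf had a difference of -0.61 ± 0.41 (adjusted p = 0.518), Tnfaip3 of -0.84 ± 0.58 (adjusted p = 0.527) and Il6 of -3.61 ± 0.87 (adjusted p = 0.0513), which the test did not call. Il6 was called with the replicate block and after quantile normalization.

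Of the 709 induced genes, 254 (35.8%) had a reduced second response, 0 an enhanced one and 455 were not called. Limma found 0 enhanced at an unadjusted p under 0.05 as well. Of the 1655 repressed genes, 222 (13.4%) had a reduced second response and 0 an enhanced one, also at an unadjusted p under 0.05. In 20 simulations with equal responses, a mean of 0 induced and 0 repressed genes were called reduced. No gene of these simulations had an interaction, so the adjustment over all genes was stricter there than in the data. The 0 therefore does not measure how many reduced calls the choice of genes by their first response could add. Induced genes had a median log2 change of 1.77 in the first response and 0.382 in the second (0.539 without the restimulated replicate C array), and the second was the smaller for 97.2% of them. Repressed genes had medians of -1.42 and -0.702 (-0.526 without that array), with the second smaller for 99%. Because these genes were chosen by their first response, the second is smaller for most of them even with equal responses. In the simulations the second was smaller for 58.7% of induced and 59.8% of repressed genes, with mean medians of 1.72 and 1.68 for induced and -1.43 and -1.39 for repressed genes. Also called in the second response, in the same direction, were 111 induced genes (86 without that array) and 222 repressed genes (90 without it). Of the genes called in the second response and not in the first, 10 were higher and 12 lower, and the interaction was called for 0 of the 10 and 1 of the 12. Without that array 7 were higher and 3 lower, and it was called for 1 of the 7 and 0 of the 3. The 1 of the 7, named after its values were seen, was Slx4ip, with a second response of 1.93 and an interaction of 1.13 without that array (1.57 ± 0.30 and 0.76 ± 0.42 with it). The 1 of the 12, also named after its values were seen, was Bcl2l11, which encodes a protein that promotes cell death. Its second response of -1.41 ± 0.32 was lost without any of 10 arrays, all except LPS once A and restimulated B (adjusted p up to 0.15), and its interaction of -2.01 ± 0.45 was lost without any of 9 arrays, all except LPS once A and restimulated B and C (adjusted p up to 0.1).

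Of 35 interferon-induced genes 10 had a lower response on restimulation, 30 adjusted over the list alone and 19 with the replicate block (camera adjusted p = 1.95e-18, adjusted p = 0.407 with an estimated correlation), among them Gbp2 at -4.83. Of 28 cytokines 8 did, 14 adjusted over the list alone, with Edn1, which encodes endothelin 1, at -4.64 (camera adjusted p = 3.62e-10, adjusted p = 0.203 with an estimated correlation). Of 26 chemokines 5 did, 9 adjusted over the list alone, with Cxcl9 at -3.07 and Ccl4 at -1.46 (camera adjusted p = 9.13e-08, adjusted p = 0.203 with an estimated correlation). Antimicrobial and acute phase genes had 7 of 21 lower, 11 adjusted over the list alone, with Cp, the copper carrier ceruloplasmin, at -4.85 and Cfb at -3.85 (camera adjusted p = 5.04e-09, adjusted p = 0.203 with an estimated correlation). Costimulatory ligands had 6 of 15 lower, 7 adjusted over the list alone, with Cd40 at -3.99, Tnfsf9 at -3.64 and Cd274 at -3.26 (camera adjusted p = 2.24e-08, adjusted p = 0.203 with an estimated correlation). Survival genes had 5 of 21 lower, 9 adjusted over the list alone, with Gadd45b at -3.01 (camera adjusted p = 4.09e-05, adjusted p = 0.203 with an estimated correlation). Glycolysis and hypoxia-induced genes had 3 of 22 lower, 5 adjusted over the list alone and 5 with the replicate block, with Pfkfb3 at -3.84 and Adm at -3.28 (camera adjusted p = 0.000172, adjusted p = 0.556 with an estimated correlation). Negative regulators had 4 of 30 lower and 1 higher, 9 and 1 adjusted over the list alone, and 7 lower with the replicate block (camera adjusted p = 0.00326, adjusted p = 0.534 with an estimated correlation). Dusp2 stood at -3.71, Cish at -2.90 and the phosphatase gene Inpp5d at 2.48.

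The interaction was called for 223 genes with a higher and 262 with a lower value. Without the restimulated replicate C array the higher genes numbered 480. They numbered 116, 109 and 74 without untreated A, B and C, 135 without LPS once C, 112 without pretreated B and 136 without restimulated B. The lower genes numbered 151, 157 and 124 without untreated A, B and C, and 174 without pretreated B and without pretreated C. Reduced induced genes numbered 150, 155 and 123 without untreated A, B and C and 166 without pretreated B. Reduced repressed genes numbered 116, 109 and 74 without untreated A, B and C, 134 without LPS once C, 111 without pretreated B, 132 without restimulated B and 464 without restimulated C.

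**Figure D3:**
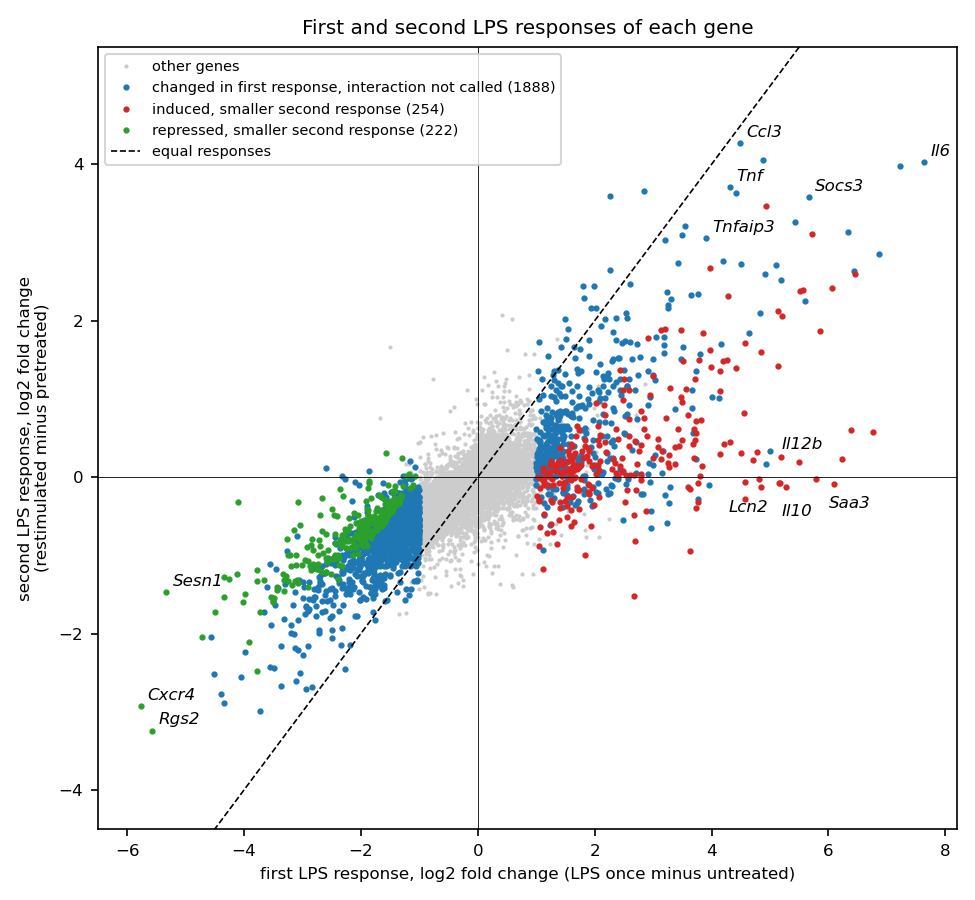
First LPS response of each of 18193 genes on the horizontal axis against its second response on the vertical axis, both as log2 fold changes, with genes coloured by class and a dashed line of equal responses. The 254 induced and 222 repressed genes with a smaller second response lie between that line and the line of no second response or beyond the latter.

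Across the 18193 genes the first and the second response, which share no array, had a Pearson correlation of 0.76 and a Spearman correlation of 0.708. Genes are not independent replicates, and these values describe the arrays. Within replicate letters A, B and C the Pearson correlation was 0.679, 0.672 and 0.651. Over the induced genes the second response rose with the first at a slope of 0.286, and of 0.34 without the restimulated replicate C array.

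The last comparison, restimulated against LPS once, asked which level the genes reached after LPS with and without pretreatment. Il10 stood -5.72 ± 0.21 log2 units from its level after LPS once (SE, n = 3 per group, limma adjusted p = 1.05e-06), Il12b -5.18 ± 0.37, Edn1 -4.81 ± 0.15 and Cd83 -4.95 ± 0.29. Il6 and Tnf were also lower, at -2.98 ± 0.61 and -1.45 ± 0.29. Higher than after LPS once were Ly6i at 3.98 ± 0.42, Sesn1 at 3.48 ± 0.44, Gpr65 at 3.43 ± 0.40, Sirpb1a at 3.09 ± 0.21 and Cfb at 2.82 ± 0.39. Ccl5, Lcn2 and Fpr2, whose second responses were called reduced, had level differences of -0.05 ± 0.14, 1.06 ± 0.60 and 0.36 ± 0.21, which were not called. For Ccl5 and Lcn2 both values may be limited by the top of the scale, and for Fpr2 the second response may be.

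Cytokines had 14 of 28 members lower and 17 adjusted over the list alone, with Il15 at -3.73 (camera adjusted p = 4.6e-11, adjusted p = 0.203 with an estimated correlation). Chemokines had 6 of 26 lower, 10 adjusted over the list alone and 10 with the replicate block, with Cxcl11 at -2.80 and Ccl4 at -2.59 (camera adjusted p = 0.000118, adjusted p = 0.31 with an estimated correlation). Costimulatory ligands had 9 of 15 lower and 11 adjusted over the list alone, with Cd40 at -3.82 and Slamf1 at -3.06 (camera adjusted p = 8.14e-08, adjusted p = 0.203 with an estimated correlation). Negative regulators had 12 of 30 lower and 2 higher, also adjusted over the list alone, with Dusp2 at -4.12 and Zfp36, which promotes decay of cytokine mRNA, at -2.34 (camera adjusted p = 8e-08, adjusted p = 0.212 with an estimated correlation). Survival genes had 7 of 21 lower, also adjusted over the list alone (camera adjusted p = 3.18e-06, adjusted p = 0.203 with an estimated correlation), and immediate-early factors 7 of 30, also adjusted over the list alone, with Ier2 at -2.64 and Myc at -1.84 (camera adjusted p = 0.000685, adjusted p = 0.239 with an estimated correlation). Interferon-induced genes had 3 of 35 lower and 2 higher, also adjusted over the list alone, and 8 lower with the replicate block (camera adjusted p = 0.00172, adjusted p = 0.799 with an estimated correlation). Camera did not call this list without the restimulated replicate C array (adjusted p = 0.0903), and did with the replicate block (7.79e-05) and after quantile normalization (0.0016). Gbp3 and Ifih1, a sensor of viral RNA, were lower at -2.54 and -2.17. Antimicrobial and acute phase genes had 2 of 21 higher and 1 lower, also adjusted over the list alone, with Ptx3 at -3.49, and 1 higher without that array (camera adjusted p = 0.249, adjusted p = 0.811 with an estimated correlation).

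In all, 451 genes were higher and 578 lower than after LPS once. Without the restimulated replicate C array 733 were higher and 434 lower, and after quantile normalization 586 were higher and 526 lower. Of the 72 called genes that the naming rule takes here, 57 kept their call without any of the 12 arrays. Of the 709 induced genes 386 (54.4%) were lower (340 of 728 without the restimulated replicate C array), 5 higher and 318 not called. The 5, named after their values were seen, were Cfb, Pilra at 2.14 ± 0.31, Pilrb1 at 1.83 ± 0.23, Irf7 at 1.64 ± 0.39 and Marco at 2.35 ± 0.61. Irf7 and Marco were not called without LPS once B or C or restimulated A or B (adjusted p up to 0.082 and 0.093). Of the 1655 repressed genes 386 (23.3%) were higher and 6 lower, and 589 were higher without that array. In the 20 simulations with equal responses a mean of 29 induced genes was called lower in level and 75.2 higher, and of repressed genes 11.6 higher and 62.8 lower. Of the 254 induced genes with a reduced second response, 204 were also lower in level, 49 were not called in level and 1, Cfb, was higher. Pretreatment alone had raised 24 of the 49 and 2 of the 204, Cd274 by 1.95 ± 0.34 and Nupr1 by 1.91 ± 0.31. Both calls were lost without untreated A or C or pretreated B or C, and that of Cd274 also without untreated B or LPS once B or C (adjusted p up to 0.12 and 0.093). A further 182 induced genes were lower in level without a call in the interaction.

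**Figure D4:**
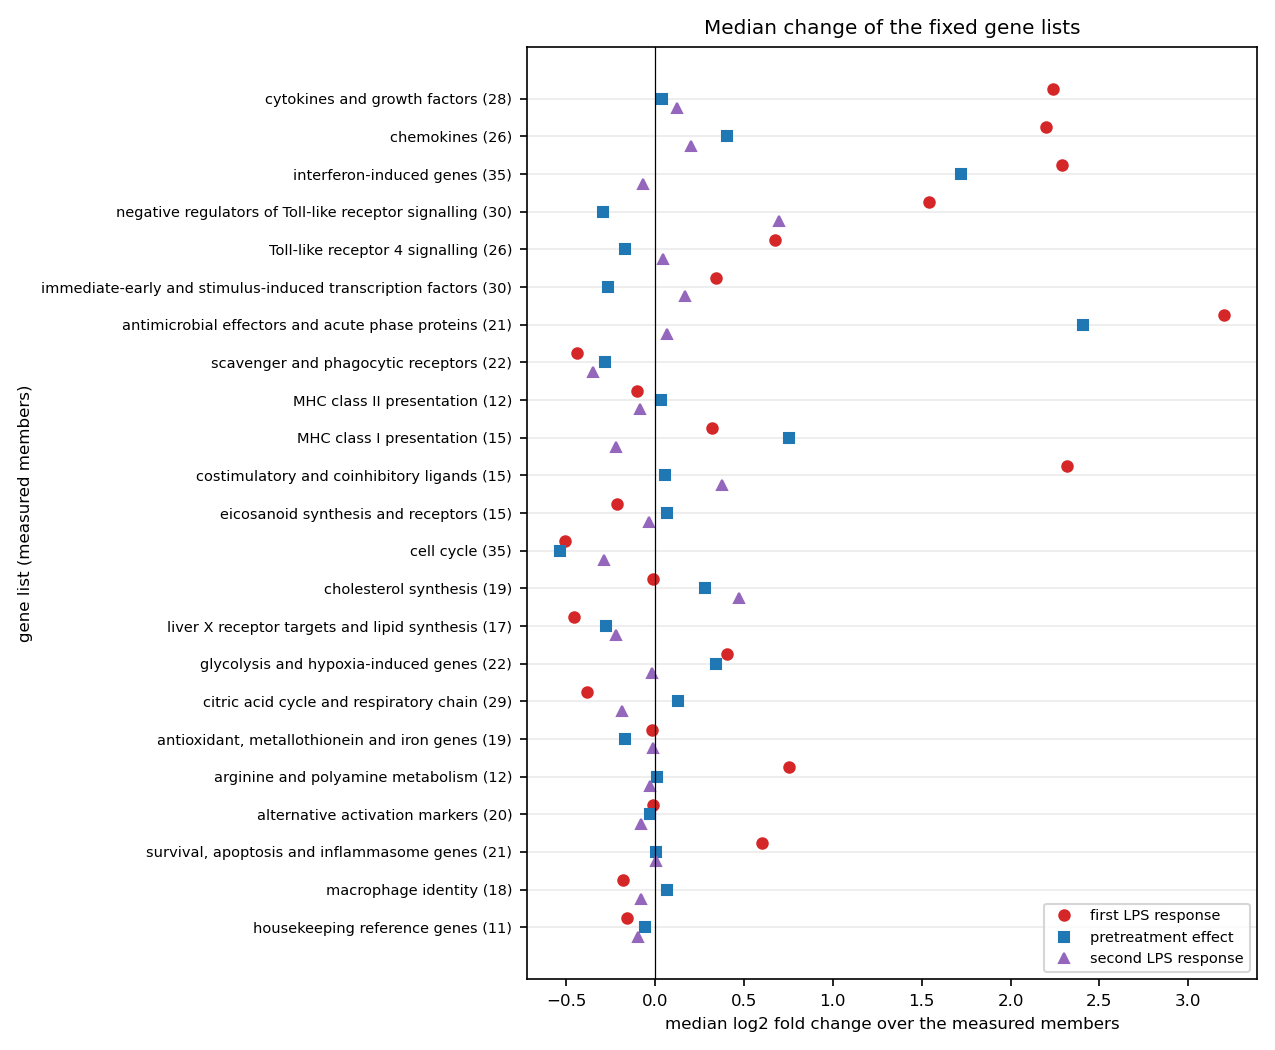
Median log2 fold change over the measured members of each fixed gene list, other cell types left out, in the first LPS response (circles), after pretreatment (squares) and in the second LPS response (triangles), with the number measured in parentheses. Interferon-induced genes had medians of 2.29, 1.72 and -0.0682, and negative regulators of Toll-like receptor signalling of 1.54, -0.291 and 0.698.

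Of 82 measured markers of other cell types in 8 lists, limma called 2 higher and 1 lower after LPS once, 0 after pretreatment, 0 in the second response, 1 lower in the interaction, and 1 higher and 1 lower in level. At an unadjusted p under 0.05, 21 were higher and 1 lower after LPS once, 7 and 1 after pretreatment, 4 and 1 in the second response, 0 and 6 in the interaction, and 1 and 7 in level. With the replicate block 1 was called higher and 1 lower after pretreatment, and 1 higher and 4 lower in level. Hdc, which encodes the enzyme that makes histamine and stands on the mast cell and basophil list, rose by 3.70 ± 0.20 after LPS once, with an interaction of -3.45 ± 0.29 and a level difference of -3.10 ± 0.20. The other called markers were Pdgfrb, a receptor of stromal cells, at 2.44 ± 0.82 and Il7r, a receptor of T cells, at -1.96 ± 0.64 after LPS once, and Bst2 at 1.36 ± 0.34 in level. Bst2 stands on the dendritic cell list and also on the list of interferon-induced genes. Pdgfrb was not called without untreated A or C, any LPS once array, pretreated A or B or restimulated A, Il7r without any untreated or LPS once array or pretreated C, and Bst2 without LPS once B or C or restimulated A or B (adjusted p up to 0.14, 0.11 and 0.09). The list of 10 mast cell and basophil genes stood above other genes after LPS once (camera adjusted p = 0.0162, adjusted p = 0.212 with an estimated correlation) and below them in the interaction (camera adjusted p = 0.0112, adjusted p = 0.211 with an estimated correlation). Its median log2 changes were small, 0.172 and -0.166, and Hdc was its 1 called member in each. At an unadjusted p under 0.05, 6 of the 10 were higher after LPS once, 1 after pretreatment and 0 in the second response. Medians were also small for the NK cell list after LPS once (0.145) and the dendritic cell list after pretreatment (0.114). The list of 9 NK cell markers stood above other genes after LPS once (camera adjusted p = 0.0473, adjusted p = 0.547 with an estimated correlation), with 0 called, 4 higher at an unadjusted p under 0.05, and no call by camera without the restimulated replicate C array (adjusted p = 0.0643) or after quantile normalization (0.209). The list of 11 dendritic cell markers stood above them after pretreatment (camera adjusted p = 0.0328, adjusted p = 0.247 with an estimated correlation), with 0 called, 3 higher at an unadjusted p under 0.05, and no call by camera after quantile normalization (adjusted p = 0.11). Of 18 macrophage identity genes 2 fell after LPS once, Cx3cr1, the fractalkine receptor, at -3.09 and Mertk, which takes part in the uptake of dying cells, at -3.54, also adjusted over the list alone (camera adjusted p = 0.216, adjusted p = 0.637 with an estimated correlation). Of 11 housekeeping genes 1 fell, Gusb at -1.16, also adjusted over the list alone (camera adjusted p = 0.216, adjusted p = 0.811 with an estimated correlation).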

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

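The tests of the spike-in controls, of quantile normalization, of the 5′ end and of splits that keep the letters were chosen only after the result was seen, and the other tests of this part before. What picked out the first set of results was a test of the difference between the first and the second LPS response. It called 223 genes with a higher and 262 with a lower second response, among them 254 induced and 222 repressed genes whose second response was reduced. Of 100 drawn splits of the 12 arrays 1, the real one, gave as many as 485 changed genes, and the highest other gave 6. For the 254 reduced induced genes the same held with 1 of 100, and the highest other gave 1. These splits ignore the letters, which pair the arrays, and mix groups that LPS separates. Of 100 drawn splits that keep the letters, 5 gave as many as 485 changed genes, with 2904 in the highest other, so chance assignment is not excluded for this count. As many as 254 reduced induced genes came from 4 of 100, with 479 in the highest other, 1 split short of 5%, so it is not firmly excluded for that count either. The 4 and 3 other splits that reached these counts set stimulated against unstimulated or pretreated against other arrays in 2 letters or more, as 24 of the 100 did, and so carry those effects into the interaction.

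The comparisons of 2 groups have 10 splits of their 6 arrays, too few for a share under 0.05, and in each the count was reached by 1 split, the real one. Fitted on those arrays alone, the real split called 2384 genes for the first response, 146 for the pretreatment effect, 1 for the second response and 592 for the level after LPS, and the highest other split 0. Because the letters pair the arrays, the real split was also set against the 4 of 10 splits that part all 3 pairs, where the highest other gave 0, as did the splits that do not part them. Every other split mixes the 2 real groups, so a difference between these widens the spread and leaves few calls. The 0 of the other splits therefore adds no support.

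Among the genes with the most negative interactions were U90926 (-6.18), Shisa3 (-6.00), Saa3 (-5.81), Mmp13 (-5.79), Il10 (-5.40), Il12b (-5.29), Ccl5 (-5.24), Lcn2 (-5.22) and Il1rn (-4.98), all as log2 differences between the 2 responses. The most positive were Sesn1 (3.86), Gpr65 (3.79), Cd300lb (3.06), Zfp36l2 (2.96), N4bp2l1 (2.87), Cxcr4 (2.83), Cytip (2.81), Susd3 (2.76), Dapk1 (2.75) and Tmem86a (2.66). Among secreted factors and their receptors the values were -3.86 for Cxcl10, -3.74 for Fpr2, -4.64 for Edn1, -3.07 for Cxcl9 and -1.46 for Ccl4. Interferon-induced and acute phase genes had -4.83 for Gbp2, -4.45 for Ifit1, -4.92 for Oasl1, -4.49 for Cmpk2, -4.85 for Cp and -3.85 for Cfb. Costimulatory ligands had -3.99 for Cd40, -3.64 for Tnfsf9, -3.26 for Cd274 and -3.20 for Slamf1. Regulators of signalling and transcription had -3.71 for Dusp2, -2.90 for Cish, -1.39 for Nfkbib, 2.48 for Inpp5d, -2.47 for Rel, -1.88 for Map3k8, -2.22 for Ier2 and -1.15 for Klf6. Metabolic and stress genes had -3.84 for Pfkfb3, -3.28 for Adm, -3.01 for Gadd45b, 1.99 for Fads1, -3.45 for Hdc, -2.36 for Slc39a14 and -1.72 for Sod2, and the receptors Olr1 and Fcgr2b -3.02 and -2.76.

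Of the 64 genes that the naming rule takes from the interaction, 42 kept their call without any of the 12 arrays, and the highest adjusted p among the other 22 was 0.11. Among those given above, Il1rn lost its call without untreated C (adjusted p = 0.056), Cxcl10 without untreated A or C, and Mmp13 without untreated A or C or LPS once B or C. Zfp36l2 lost it without untreated B or C or pretreated B, Cytip without untreated A or B or LPS once C, and Dapk1 without any untreated array, pretreated B or C or restimulated B. Ifit1 lost it without untreated A or C, LPS once C, pretreated A or B or restimulated B, Cmpk2 without these arrays or untreated B, and Oasl1 without these or pretreated C. Cd300lb lost it without any of 10 arrays, all except LPS once A and restimulated C, and Cxcr4 without any untreated, LPS once or pretreated array. The highest adjusted p was 0.062 for Cxcl10, 0.068 for Mmp13, 0.059 for Zfp36l2, 0.058 for Cytip, 0.066 for Dapk1, 0.071 for Ifit1, 0.083 for Cmpk2, 0.08 for Oasl1, 0.077 for Cd300lb and 0.11 for Cxcr4.

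A second set of results came from probe sets that the comparisons of the report did not use, where a signal appeared above the untreated arrays. Of 9160 unnamed probe sets, 170 were higher after LPS once, up to 37.3-fold, and 9 after pretreatment. Of 932 probe sets with several symbols, 34 were higher after LPS once and 10 after pretreatment.

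The restimulated replicate C array had lower signals over the genes of mid-range intensity, at a median of -0.52. Weaker labelling or hybridisation is a candidate explanation, since 24 mid-range spike-in controls, which do not come from the cells, had a median of -0.33 and 22 of them were lower, against medians of -0.16 to 0.22 on the other 11 arrays, restimulated A and B being compared with each other only. The share of lower controls, 91.7%, argues against lower transcript levels as the whole cause. Because the controls moved less than the genes, a part from the cells stays open.

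In the first response 709 genes were higher and 1655 lower. Array-wide scaling as the whole cause is argued against by quantile normalization, after which 38.9% of the changed genes were higher (39.3% at most with an array left out). Weaker labelling or hybridisation of the LPS once arrays would lower spike-in controls, whose median difference was -0.05 and -0.07 at the lowest in a replicate. Both are argued against as the whole cause only. The controls were taken as 1 set, so weaker labelling was not tested apart from weaker hybridisation. A loss of signal from the 5′ end in LPS once A and C would spare replicate B. The ratio of 5′ to 3′ signal of actin was 0.588 and 0.518 in these 2 and 0.711 in B, against 0.654 to 0.745 in untreated cells. Over all genes, 69.8% of those that differed at least 2-fold between LPS once and untreated were lower in B, against 64.5% in A and 69.9% in C. Because B is a single replicate this excludes nothing, and a loss of 5′ signal stays open beside an effect of LPS, which the design names. The interaction and the level after LPS use the same arrays and the restimulated ones, at 0.884, 0.824 and 0.571 in A, B and C, so differences in 5′ signal stay open there as well.

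Of the 254 induced genes with a reduced second response, 50 were not lower than after LPS once. After pretreatment 3 of the 50 (6%, exact 95% interval 1.25% to 16.5%) had a mean intensity above 8000, where the highest on any array was 16570. The 3 were Saa3, Ccl5 and Lcn2, and the median of the 50 was 1300. Few of these genes therefore started near the top of the scale. The count leaves out genes that started lower and would pass the top with a second response as large as the first, such as Fpr2. A ceiling thus stays open for more genes than the 3, and the test does not exclude it as the whole cause. The median pretreatment effect of the 50 was 1.58, against -0.02 for the 204 genes that were lower. The level difference minus the interaction equals the pretreatment effect by construction, so a raised start and a reduced second response are not separate observations here. A lasting effect of the pretreatment may explain the pattern, which stays a hypothesis.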

How the results depend on the processing

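Array weights, and the replicate block without the restimulated replicate C array, were tests chosen only after the result was seen, and all other alternatives were planned. The counts of induced genes with a reduced second response and of induced genes lower in level moved by over 1.5 times under a changed threshold, and the first also in leave-one-out fits. The other alternatives run for both left them within 1.5 times, and fits of only the groups compared gave no value for either. Except where stated, the cause of a change was not tested. The number of arrays limits the precision, and changes of dim genes are understated.

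With a pseudocount of 64, 34 genes were lower after pretreatment, 154 lower in the second response, 129 higher in the interaction and 273 higher in level, and 129 repressed genes had a reduced second response and 221 a higher level. A larger pseudocount shrinks the changes of dim genes by construction. Quantile normalization gave 81 higher genes after pretreatment and a correlation of 0.737 between the first and the second response. Without the dimmer 50% of genes 80 were higher after pretreatment, where fewer genes were adjusted for. With the mean of all probe sets of a gene, 140 were lower in the second response, 124 higher in the interaction and 287 higher in level, and of the repressed genes 124 were reduced and 239 higher in level. With only the arrays of the groups compared, 1 gene was higher and 0 lower in the second response (518 and 2068 at limma's unadjusted p under 0.05), and 251 were higher and 341 lower in level. Those fits have fewer arrays and fewer degrees of freedom.

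With the replicate block, 100 genes were higher and 97 lower after pretreatment, 53 of each shared with the unblocked fit. The block called 61 of the 61 gene list tests called without it and 6 more. The added tests were arginine metabolism in the first response and in level, cholesterol synthesis in the interaction, and the cell cycle, liver X receptor and stromal lists in level. Of the named genes' results, 26 gained a call with the block and 2 lost one. The number of called members rose in 58 of the 155 pairs of a gene list and a contrast and fell in 0, by 9 genes at most, and the report gives some of these counts.

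Thresholds change counts by construction. With no fold minimum the first response had 2366 higher and 3700 lower genes, pretreatment 86 higher, the second response 558 lower, the interaction 348 higher and the level 1357 higher and 1306 lower. Of induced genes 901 were then lower in level, and of repressed genes 348 were reduced and 1218 higher in level. At an adjusted p under 0.01, 25 genes were higher and 21 lower after pretreatment, 49 and 35 in the second response, and 52 and 89 in the interaction, with 89 induced and 52 repressed genes reduced. At a minimum of 4-fold the first response had 300 higher and 316 lower genes, pretreatment 32 and 16, the second response 43 and 25, the interaction 35 and 123 and the level 44 and 166. Of induced genes 109 were then reduced and 111 lower in level, and of repressed genes 35 were reduced and 30 higher in level.

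Array weights, which gave the restimulated replicate C array 0.138 and the others 0.515 to 2.23, called 130 genes higher and 159 lower after pretreatment, 198 higher in the second response, 515 higher in the interaction and 736 higher in level. Of repressed genes 496 were then reduced and 583 higher in level. The replicate block without that array called 118 higher and 156 lower after pretreatment, 84 lower in the second response, 586 higher in the interaction and 761 higher in level, with 565 repressed genes reduced and 618 higher in level.

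With each array left out in turn, the first response had 644 to 728 higher and 1540 to 1813 lower genes, pretreatment 26 to 77 and 25 to 75, the second response 60 to 167 and 35 to 463, the interaction 74 to 480 and 124 to 292, and the level 306 to 733 and 434 to 652. Reduced induced genes numbered 123 to 277, induced genes lower in level 333 to 404, reduced repressed genes 74 to 464 and repressed genes higher in level 262 to 589. The correlation of the 2 responses lay between 0.697 and 0.771. A group left with 2 arrays took part in the common estimate of the spread.

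Among 61 gene list tests called by camera, 0 passed with an estimated correlation, 42 passed in fry, 56 after quantile normalization and 60 with the mean of probe sets. Without the dimmer 50% of genes 135 of the 155 tests could be run. There 50 of the 61 passed, 8 did not and the rest had no value. In all these settings 0 took the opposite direction. Of the named genes' results, 2 reversed. Without probe sets whose targets may be shared, the pretreatment effect of Sulf2 was 0.09 in place of -2.23 and that of Trem2 0.22 in place of -1.25. Each then rests on another probe set, by construction. Calls of named genes were lost in 2 results with a pseudocount of 1, 19 with 64, 7 after quantile normalization, 3 after median centring, 18 with the mean of probe sets and 6 without shared probe sets. They were lost in 70 with only the arrays compared, 103 at an adjusted p under 0.01, 75 at 4-fold, 5 with array weights and 20 with the block without the restimulated replicate C array, and in 0 with a prior that follows the mean and with no fold minimum. With dim genes left out 0 were lost among the results that kept a value, which 23 lacked under the milder filter and 57 under the stricter one, as 12 did without shared probe sets and 105 with only the arrays compared. Background correction was not varied, because the values were already processed.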

Other observations

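The tests of how often the induced members of a list kept a second response were chosen only after the result was seen. Lipid and energy metabolism genes were compared between restimulated cells and cells given LPS once. Of 19 cholesterol synthesis genes 2 were higher in level, 3 adjusted over the list alone, 4 with the replicate block and 6 without the restimulated replicate C array (camera adjusted p = 0.000922, adjusted p = 0.63 with an estimated correlation). Dhcr7, the enzyme of the last step to cholesterol, stood 1.40 ± 0.21 log2 units higher (SE, n = 3 per group, limma adjusted p = 0.00222), and had changed by -1.77 after LPS once. Mvd, an enzyme of the mevalonate pathway, stood 1.26 ± 0.33 higher, a call lost without LPS once A or C or restimulated A or B (adjusted p up to 0.11). Of 17 liver X receptor targets and lipid synthesis genes 3 were higher, also adjusted over the list alone, with Fads1 at 2.10 (camera adjusted p = 0.0552, adjusted p = 0.578 with an estimated correlation). Camera called this list in level with the replicate block (0.0376), after quantile normalization (0.0491) and without the restimulated replicate C array (0.0206). Of 29 genes of the citric acid cycle and respiratory chain 1 was higher, Sdhb at 1.08, and 16 were higher at an unadjusted p under 0.05 (camera adjusted p = 6.1e-06, adjusted p = 0.556 with an estimated correlation).

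Several lists went both ways in the first LPS response. Of 19 antioxidant, metallothionein and iron genes 6 rose and 2 fell, also adjusted over the list alone, with the cystine transporter gene Slc7a11 at 5.60, the metal transporter gene Slc39a14 at 3.98 and the metallothionein Mt2 at 3.64 (camera adjusted p = 0.464, adjusted p = 0.917 with an estimated correlation). Of 15 genes of eicosanoid synthesis and receptors 4 rose and 3 fell, also adjusted over the list alone. Ptges and Ptgs2, enzymes of prostaglandin synthesis, rose by 5.51 and 5.43 (camera adjusted p = 0.713, adjusted p = 0.886 with an estimated correlation). Of 22 scavenger and phagocytic receptors 5 rose and 5 fell, also adjusted over the list alone, with Olr1, which binds oxidised lipoprotein, at 4.42 and Mertk at -3.54 (camera adjusted p = 0.619, adjusted p = 0.928 with an estimated correlation). Of 20 alternative activation markers 3 rose and 2 fell, also adjusted over the list alone, with Ccl22 at 2.99 and Pparg at -2.10 (camera adjusted p = 0.713, adjusted p = 0.827 with an estimated correlation). The medians and means of the antioxidant (-0.0163 and 0.617), eicosanoid (-0.216 and 0.513) and alternative activation lists (-0.0116 and 0.0478) differed in sign. Of 12 arginine and polyamine genes 3 rose, 4 adjusted over the list alone and 5 with the replicate block, with Slc7a2, an arginine transporter, at 4.83 and Gch1, an enzyme of tetrahydrobiopterin synthesis, at 3.48 (camera adjusted p = 0.0836, adjusted p = 0.556 with an estimated correlation), and camera's adjusted p was 0.0469 with the block and 0.0696 after quantile normalization.

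A hypothesis from these data is that induced negative regulators of Toll-like receptor signalling kept a called second response more often than other induced genes. Of the 18 induced members 12 (66.7%) were called in the second response, against 99 of 691 other induced genes (14.3%), with a two-sided Fisher exact p = 1.03e-06 and 3.18e-05 adjusted over the 31 lists. It was the 1 list of 31 past the threshold, which is consistent with the hypothesis, although the genes are not independent and the same arrays gave the pattern and its test. Of the same 18 members 12 were lower in level than after LPS once and 4 had a reduced second response. A fit of the 6 arrays of the second response alone has fewer degrees of freedom, and it was run without the replicate block. In it limma called 1 gene higher, Ccl4, which is not on this list. Of 29 induced interferon-induced genes 0 were called, against 111 of 680 (16.3%), with a Fisher exact p of 0.015 and 0.155 after adjustment, so a lower share in this list was not shown.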
